A study of Mus musculus with 12 samples.

How the data were processed

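RNA-seq counts were analysed for 12 libraries of sorted mouse CD4 T cells labelled as regulatory T cells: 2 genotypes by 2 CD25 gates with 3 libraries each. Per the labels' protocols, cells of spleen and of inguinal, cervical and brachial lymph nodes were enriched for CD4 and sorted for a further surface marker with high or low CD25, RNA was extracted with RNeasy Mini columns, and cDNA was made and amplified from 10 ng of total RNA with the SMARTer Ultra Low kit. The series' design text names Nextera XT for the libraries. This chemistry does not record the strand of a transcript, so reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies such as Hspa1a and Hspa1b may be split or dropped by the counting.

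The deposited values are whole-number counts of reads per Ensembl gene, not normalized. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4 and featureCounts 1.4.6 were used with genome build GRCm38; their settings are not given in the sources used here. The table had 21839 genes, of which 21628 were matched by Ensembl identifier to a symbol in the GENCODE vM21 annotation of GRCm38. The other 211 held 0.038% of the counts and kept their identifiers. Protein coding genes made up 20838 (95.4%), 5778 genes had no count in any library, and mitochondrially encoded genes were not analysed here. All positions are from that annotation, on the same build.

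Total counts ran from 6767828 to 23942479 per library. The 10 highest genes took 5.56% to 6.81% of the counts and ribosomal protein genes 0.63% to 0.99%. Chi-square per degree of freedom between replicates of a group ran from 21.03 to 48.1, so no pair agreed within sampling noise and each library counted once. Reads carry no molecular identifiers, so counting error alone understates the uncertainty, and the SEs here come from the spread between libraries.

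Groups came from the sample titles. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr at its defaults (minimum count 10), which kept 11766 genes holding 99.96% of the counts, robust quasi-likelihood fits (glmQLFit and glmQLFTest) over the 12 libraries with the 4 groups as levels, and Benjamini-Hochberg adjustment at 0.05. The 5 comparisons were TG minus WT in each gate, High minus Low in each genotype, and the difference of the genotype effects. Log2 fold changes are as fitted, levels are TMM-scaled CPM, and intervals are the estimate plus and minus 1.96 SE. Exact permutation of 3 against 3 libraries cannot give a two-sided p below 0.1, so single genes were tested in the model only.

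The labels give all groups replicate numbers 1 to 3 without saying what they mark. The numbers were checked as pairs by correlating each library's deviation from its group mean over all tested genes. Pairs within a group were left out. Between groups, same-numbered libraries correlated at 0.34 to 0.83 (18 pairs) and differently numbered ones at -0.688 to 0.197 (36 pairs). Of 12 libraries, 12 matched best outside their group with one of their own number, so the numbers pair the samples. The pairing comes from these data, and the fit with the replicate number as a block is given beside each result whose call or count it changes.

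Of the 31 gene lists, 26 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation beside it. They cover Treg core, activated or effector Treg, naive or resting T cell, conventional CD4, interleukin-2 and STAT5 response, TCR immediate response, costimulatory and coinhibitory receptors, helper lineage and cytokines, adhesion and chemokine receptors, interferon-stimulated genes, NF-kB, apoptosis, autophagy, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein response, heat shock, ribosomal proteins, T cell receptor alpha and beta segments, and B, myeloid or dendritic, CD8 or NK and gamma delta cells. Lists of mitochondrially encoded, sex-linked, neutrophil, plasma cell and erythroid or platelet genes were too short for a test. Lists share genes, and other-cell lists hold genes that T cells also express. Only the Treg core, interleukin-2 and conventional CD4 lists were called with an estimated correlation, in the CD25 comparisons, and of these the conventional list in TG without the block alone.

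Named genes were, per comparison and direction, the 10 largest log2 changes (5 for the difference of effects) among genes past the threshold with a mean of at least 10 CPM in the higher group, no predicted-gene symbol and no overlap between the groups; up to 4 members of each list with the smallest p were eligible, and where under 5 genes passed, the 5 with the smallest p were named as not having passed. Atg5, Il2ra, Foxp3, Icos and Ctla4 are always given. Some genes that the rule names are not reported here. For the blocked fit, the same direction in all 3 pairs replaced the no-overlap condition, a choice made after seeing the data. Genes of lists named for being called, those in counts of 6 or fewer, and Gm4951 were chosen after their values were seen where the rule did not name them.

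The edgeR fits and camera at the preset correlation were tested on simulated counts with 200 changed genes among 11766. These counts were drawn from the means, dispersions, replicate effects and library sizes of the real libraries. The other methods were not tested on simulated counts. At log2 changes of 0.5, 1 and 2, the fit without the block recovered 7.5%, 50.7% and 81.8% for genotype in CD25 High, 13.4%, 59.7% and 78.8% for genotype in CD25 Low, 9%, 56.7% and 74.2% for the gates in WT, 13.4%, 64.2% and 83.3% for the gates in TG and 0%, 26.9% and 71.2% for the difference of effects, with 0 or 1 false call. With the block the shares were 43.3%, 77.6% and 98.5%, then 44.8%, 74.6% and 90.9%, then 52.2%, 71.6% and 95.5%, then 50.7%, 85.1% and 93.9%, then 26.9%, 74.6% and 83.3%, with 6 to 15 false calls among 129 to 168. None of 20 unchanged lists was called. Beyond the replicate effects, correlation between the genes of a list was not among the inputs of the simulation. It therefore cannot show how often camera at the preset correlation falsely calls lists whose genes vary together. In the real data 8 lists in CD25 High and 11 in CD25 Low were called for genotype at the preset correlation (12 and 17 with the block). With an estimated correlation the count was 0 in each case. Alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE and upper-quartile scaling, other low-count filters, the compared libraries alone, the replicate block, leaving out marker and receptor segment genes, and leaving out each library. Fits without a numbered set of libraries, the averaged genotype effect (also with the counts of both gates summed per genotype and number) and alternatives of the blocked fit were added after seeing the data.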

Results

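Regulatory T cells (Tregs) are CD4 T cells that restrain immune responses and express the transcription factor Foxp3 and the interleukin-2 receptor chain CD25, encoded by Il2ra. The study asked what their RNA looks like when dendritic cells lack autophagy, the process by which cells digest their own contents. It used C57BL/6 mice with a loxP-flanked Atg5 gene. In mice called TG here, Cre recombinase driven by the CD11c promoter removes Atg5 from CD11c-expressing cells, mainly dendritic cells; littermates without Cre are called WT. CD4 T cells of spleen and lymph nodes were sorted for a further surface marker and for either high or low CD25. The gates used no Foxp3 stain or reporter per the labels. The 4 groups (WT High, TG High, WT Low and TG Low) held 3 libraries each, 12 in total. Total counts per library ran from 18161830 to 23942479 in WT High, from 6767828 (replicate 2) to 21382878 in TG High, from 18678438 to 20236348 in WT Low and from 19230463 to 20223658 in TG Low. Between 12370 and 14164 genes had a count in a library. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples. The Y-linked gene Ddx3y stood at 44.4, 205 and 103 CPM (of unscaled totals) in WT High replicates 1, 2 and 3. It stood at 51.7, 202 and 128 in TG Low, and the other groups had the same order. These values argue against repeated libraries of the same RNA sample within a group. Whether the numbers mark animals, pools or days is not given.

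The replicate number separated the libraries more than genotype or gate did. The first principal component held 53.2% of the variance and set the 4 libraries numbered 1 apart from the other 8, and the second held 13.3% and parted the numbers 2 and 3. With the 4 groups held constant, 3239 of 11766 tested genes differed between replicate 1 and the other replicates (1976 higher and 1263 lower in replicate 1). Markers of other cells were part of this difference. All 17 tested B cell genes were higher in replicate 1 (median log2 difference 3.62), as were 13 of 17 myeloid or dendritic cell genes and 10 of 12 CD8 T or NK cell genes. Genes of activated or effector Tregs (39 of 40 higher, median 1.41) and of the cell cycle (34 of 34 higher, median 2.48) moved the same way, and 15 of 22 naive or resting T cell genes were lower. Because libraries with the same number varied together, each comparison is given without and with the replicate number as a block.

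**Figure D1:**
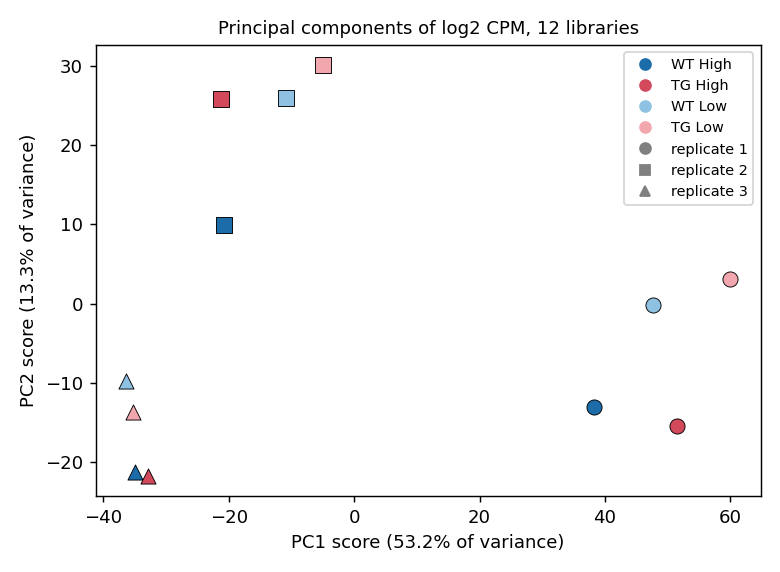
Scores of the 12 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, which held 53.2% and 13.3% of the variance; colours give the 4 groups and shapes the replicate number. The 4 libraries numbered 1 (circles) lie between 38.2 and 60 on the first component, and the other 8 lie below 0.

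Atg5, the gene removed in CD11c-expressing cells, was present in all 12 sorted libraries. It lies on chromosome 10 at 44268358 to 44364291 (GRCm38, plus strand, protein coding). Its level was 33.3 ± 2.08 CPM in WT High, 38.6 ± 4.14 in TG High, 37.0 ± 0.579 in WT Low and 38.6 ± 2.49 in TG Low (mean ± SD, n = 3 each). The lowest library was WT High replicate 2 at 32.0 CPM and the highest TG High replicate 3 at 41.5 CPM. The TG to WT difference was 0.21 on the log2 scale in CD25 High (SE 0.10, edgeR adjusted p = 1) and 0.06 in CD25 Low (SE 0.10, adjusted p = 1). T cells were not the target of the deletion, so this level does not test the genotype labels.

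CD25 High against CD25 Low cells of WT mice. The comparison asks which genes go with the surface level of CD25. In CD25 High cells the Treg core list and the interleukin-2 and STAT5 response list were each higher as a set. Il2ra itself was 2.04-fold higher, 1190 ± 118 against 590 ± 131 CPM (mean ± SD, n = 3 each), and Il2rb, another chain of the interleukin-2 receptor, was 1.81-fold higher, 1851 ± 44.8 against 1025 ± 103 CPM. Foxp3 was 1.43-fold higher (1550 ± 106 against 1086 ± 101 CPM). Genes of conventional CD4 T cells were lower as a set, and with the block the receptor genes Cxcr3, Ccr2 and Vipr1 were called lower. Markers of other cells moved with the same contrast, and the share of such cells in these calls was not tested.

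Without the block, edgeR called 6 of 11766 genes in WT, 5 higher and 1 lower. These were Il2rb (log2 0.85, SE 0.09, adjusted p = 0.00631), Gpr83 (log2 1.12, SE 0.15, adjusted p = 0.0279), Rragd (log2 0.91, SE 0.12, adjusted p = 0.0277), Zscan29 (log2 0.87, SE 0.12, adjusted p = 0.0363), Mcub (log2 0.74, SE 0.11, adjusted p = 0.0392) and, lower, Vipr1 (log2 -1.51, SE 0.18, adjusted p = 0.0173). Gpr83 is a Treg-enriched receptor, Rragd a GTPase that signals amino acid supply to mTORC1, Mcub a subunit of the mitochondrial calcium channel and Vipr1 the receptor for vasoactive intestinal peptide. Il2ra (adjusted p = 0.0634) and Foxp3 (adjusted p = 0.118) did not pass in that fit, nor did the lower Klhl5, Dapl1, Chd7, Fasl and F2rl1, which had the smallest p among genes lower in CD25 High with a mean of at least 10 CPM in the higher group (adjusted p = 0.0835 for Klhl5 to 0.349 for F2rl1). With the block the count was 192, 117 higher and 75 lower, and it contained those 6. Il2ra (log2 1.03, SE 0.09, adjusted p = 1.42e-05) and Foxp3 (log2 0.51, SE 0.08, adjusted p = 0.00212) were then among the called genes. Il2ra lies on chromosome 2 at 11642807 to 11693193 (plus strand), Il2rb on chromosome 15 at 78479256 to 78495271 (minus strand) and Foxp3 on the X chromosome at 7573644 to 7595245 (plus strand), all protein coding in GRCm38.

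Among the 23 Treg core genes in WT, 2 passed over all genes and 13 when adjusted over the list alone, all higher in CD25 High (median log2 0.475). With the block 16 passed over all genes and 18 when adjusted over the list alone. The list was higher as a set (camera adjusted p = 1.81e-49, and adjusted p = 0.000658 with an estimated correlation). Besides Il2ra, Il2rb, Gpr83 and Foxp3, the blocked fit called Lrrc32, which anchors latent TGF-beta on the Treg surface (2.08-fold, 665 ± 90.4 against 322 ± 64.6 CPM, adjusted p = 1.42e-05), Socs2, a target of STAT5 (2.14-fold, adjusted p = 8.02e-05), the TNF receptor family members Tnfrsf4 (1.66-fold, adjusted p = 0.000474) and Tnfrsf18 (1.34-fold, adjusted p = 0.0176), the inhibitory receptor Ctla4 (1.5-fold, adjusted p = 0.00657) and the transcription factor Ikzf4 (1.47-fold, adjusted p = 0.00115). Capg, Entpd1, Hopx, Izumo1r, Plagl1 and Swap70 made up the rest of the 16. Ikzf2, which encodes Helios, had 217 ± 12.1 CPM in CD25 High and 191 ± 58.2 CPM in CD25 Low (adjusted p = 0.912 with the block).

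The interleukin-2 and STAT5 response list was also higher in WT CD25 High cells (camera adjusted p = 1.19e-17, and adjusted p = 0.000453 with an estimated correlation). Of its 24 genes, 6 of which are also Treg core genes, 1 passed without the block (5 when adjusted over the list alone) and 8 with it (13 when adjusted over the list alone). The 8 held Cish, an inhibitor of cytokine signalling (1.54-fold, adjusted p = 0.00231), Bcl2l1, which encodes the survival protein Bcl-xL (1.27-fold, adjusted p = 0.0367), and Tnfrsf9 (1.45-fold, adjusted p = 0.0446). The NF-kB response list was higher (camera adjusted p = 0.00405 without and 0.000153 with the block, but adjusted p = 0.191 and 0.38 with an estimated correlation), with Rel, Map3k8 and Cd83 called in the blocked fit. Cell cycle genes passed as a set with the block alone (29 of 34 positive, camera adjusted p = 0.000815, 0.547 with an estimated correlation), and 1 of them was called. Leaving out WT Low replicate 1 ended the NF-kB call without the block (adjusted p = 0.0687) and the cell cycle call with it (0.482), as did leaving out WT High replicate 1 for the cell cycle (0.0563).

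Among called genes with a mean of at least 10 CPM in the higher group and the same direction in all 3 pairs, the largest increases in the blocked WT fit were Drc1 (log2 1.81, SE 0.24), Pla2g4f (log2 1.75, SE 0.17), Myb (log2 1.55, SE 0.21), Matn2 (log2 1.36, SE 0.20), Rasip1 (log2 1.36, SE 0.17), Selp (log2 1.23, SE 0.26), Slc22a2 (log2 1.19, SE 0.18), Gpr83, Dgat2 (log2 1.13, SE 0.19) and Socs2, with adjusted p from 3.37e-05 for Pla2g4f to 0.0207 for Selp. Myb is a transcription factor of haematopoietic cells and stood at 48.3 ± 8.70 against 17.8 ± 9.57 CPM. Pla2g4f, a phospholipase gene, stood at 24.5 ± 6.69 against 7.37 ± 2.46 CPM.

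The conventional CD4 T cell list was lower in WT CD25 High cells (17 genes, median log2 -0.24, camera adjusted p = 3.3e-08, and adjusted p = 0.00458 with an estimated correlation). No member passed without the block, 3 passed when adjusted over the list alone, and 5 were called with it. These were Pde3b, a phosphodiesterase that Foxp3 represses (log2 -1.52, SE 0.24, adjusted p = 0.0043), Dapl1 (log2 -1.35, SE 0.21, adjusted p = 0.0043), Cd40lg, a helper T cell ligand (log2 -0.61, SE 0.11, adjusted p = 0.00815), Igfbp4 and Ly6c1. Dapl1, Igfbp4 and Ly6c1 also belong to the naive or resting T cell list, which was lower as a set (16 of 22 negative, camera adjusted p = 0.000137, 0.74 with an estimated correlation). Variable segments of the T cell receptor alpha chain were lower in 42 of 46 cases (median log2 -0.22, camera adjusted p = 8.37e-05, 0.158 with an estimated correlation, no single segment called). Those of the beta chain were lower in 18 of 21 cases (camera adjusted p = 0.0383 without the block, 0.163 with it, 0.815 with an estimated correlation), and 1 of them was called higher with the block. Without the block, leaving out WT High replicate 1 ended the naive or resting call (adjusted p = 0.115), and leaving out WT High replicate 2 or WT Low replicate 3 ended the beta chain call (0.157 and 0.3).

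Within the same limits the largest decreases in the blocked WT fit were Pde3b, Vipr1, Il9r (log2 -1.46, SE 0.19), Cxcr3 (log2 -1.46, SE 0.20), Myo1f (log2 -1.40, SE 0.25), Rflnb (log2 -1.37, SE 0.10), Dapl1, Ccr2 (log2 -1.29, SE 0.20), Fasl (log2 -1.23, SE 0.21) and Acpp (log2 -0.96, SE 0.16). Rflnb had the smallest adjusted p of the fit, 7.42e-06, at 56.7 ± 24.2 against 143 ± 41.9 CPM. Cxcr3, a chemokine receptor of type 1 effector cells, stood at 13.0 ± 12.8 against 35.2 ± 34.3 CPM. Genes of adhesion and chemokine receptors were lower as a set with the block (camera adjusted p = 8.33e-05, 0.352 with an estimated correlation), with Cxcr3, Ccr2, Itgb1, Ly6a, Gpr183 and Gpr15 called lower and Ccr9 called higher. The activated or effector Treg list (3 called lower, 2 higher, camera adjusted p = 0.00149, 0.571 with an estimated correlation) and the helper T lineage list (Cxcr3 called lower, camera adjusted p = 0.000508, 0.394 with an estimated correlation) passed with the block alone. Leaving out WT High replicate 1 ended the effector and helper calls (adjusted p = 0.503 and 0.0681), and leaving out WT Low replicate 2 the effector call (0.228).

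Markers of other cells moved with the same contrast in WT. The B cell list was lower in CD25 High in 3 of 3 pairs of libraries, by mean log2 differences of -0.38, -0.56 and -0.32 (camera adjusted p = 0.000508 with the block, 0.453 with an estimated correlation). The myeloid list differed by -1.53, -0.47 and 0.02 (0.000632 and 0.38 likewise). The myeloid markers Csf1r and C1qb stood at 16.1 and 11.9 CPM (of unscaled totals) in WT Low replicate 1. In WT High replicate 1 they stood at 0.11 and 0, and in WT Low replicate 2 at 0.0535 and 0. CD8 T or NK cell genes were lower and passed with the block alone (camera adjusted p = 8.33e-05, 0.38 with an estimated correlation), with mean differences of -1.33, -1.21 and 0.27 in the 3 pairs. Their direction turned when the 4 libraries numbered 1 were left out (adjusted p = 0.209 with the block). The NK receptor genes Ncr1 (log2 -3.46), Klrb1c (log2 -3.31), Klrd1 (log2 -3.24) and Klrk1 (log2 -3.12) were called with the block, at means under 4 CPM in both gates. Leaving out WT High replicate 1 ended the myeloid and CD8 or NK calls (adjusted p = 0.308 and 0.0503), and leaving out WT High replicate 2 the B cell call (0.0593). The 13 lists that did not pass with the block were those of TCR immediate response, costimulatory receptors, interferon-stimulated genes, apoptosis, autophagy, glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein response, heat shock, ribosomal proteins, beta chain segments and gamma delta T cells (camera adjusted p = 0.0617 to 0.598). Without the 4 libraries numbered 1, the count of called genes in WT was 0 without the block and 49 with it, and leaving out WT High replicate 1 or WT Low replicate 1 alone gave 96 or 87 with the block. Without the block the count was 0 without WT High replicate 1, WT High replicate 2 or WT Low replicate 1, 1 without WT High replicate 3 or WT Low replicate 2, 2 without TG High replicate 3 and 3 without TG High replicate 2. The Treg core, interleukin-2 and conventional CD4 lists stayed past the threshold in all 16 settings in which they were recomputed.

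**Figure D2:**
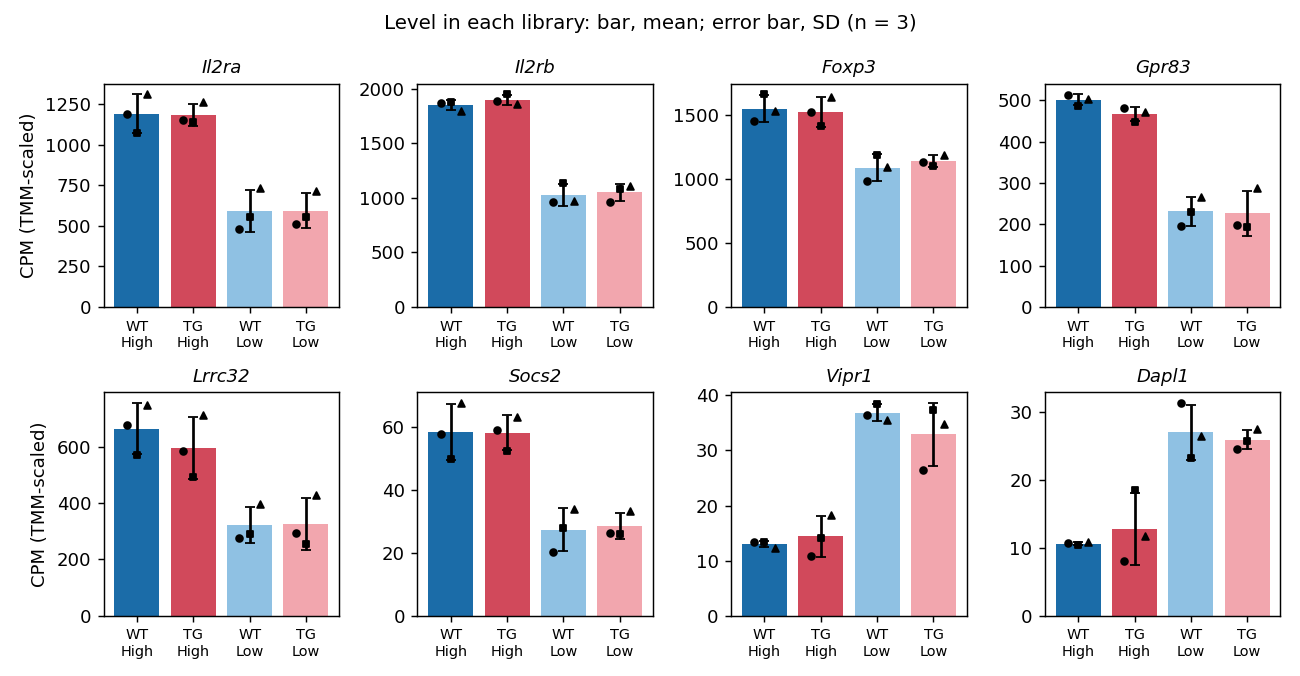
Level of 8 genes in CPM (y axis) in the 4 groups (x axis); bars give the mean, error bars the SD, and symbols the 3 libraries of a group (circle, replicate 1; square, replicate 2; triangle, replicate 3). In both genotypes the 6 genes Il2ra, Il2rb, Foxp3, Gpr83, Lrrc32 and Socs2 were higher in CD25 High, and Vipr1 and Dapl1 were lower.

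CD25 High against CD25 Low cells of TG mice. In mice whose dendritic cells lacked Atg5, the Treg core and interleukin-2 response lists were higher and the conventional CD4 list lower in CD25 High. The last did not pass with the block and an estimated correlation (adjusted p = 0.106). Il2ra was 2.01-fold higher in CD25 High (1183 ± 67.9 against 593 ± 108 CPM, mean ± SD, n = 3 each) and Il2rb 1.8-fold (1899 ± 47.6 against 1054 ± 77.3 CPM). Foxp3 was 1.34-fold higher, 1525 ± 114 against 1140 ± 48.7 CPM. With the block Rflnb, Cxcr3, Vipr1, Fasl and Pde3b were called lower. As in WT, markers of other cells moved with the contrast, and the share of such cells in these calls was not tested.

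Without the block edgeR called 1 gene in TG, Il2rb (log2 0.85, SE 0.09, adjusted p = 0.00657). Zscan29 and Gpr83 (adjusted p = 0.0704 for both), Rragd (0.0739), Mcub and Il2ra (0.0819 for both) came next among the higher genes, and Vipr1 (0.0739), Anp32a (0.0819), Thy1 (0.0986), Fasl (0.193) and Chtf8 (0.21) among the lower ones, and none of these passed. With the block the count was 198, 116 higher and 82 lower. Il2ra (adjusted p = 2.14e-05) and Foxp3 (0.0114) then passed, while Ctla4 (log2 0.42, SE 0.11, adjusted p = 0.0613) and Icos (log2 -0.38, SE 0.17, adjusted p = 0.398) did not. In WT, Icos had an adjusted p of 0.806 with the block.

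The Treg core list was higher in TG CD25 High cells (median log2 0.39, camera adjusted p = 3.03e-26, and adjusted p = 0.00564 with an estimated correlation). Of its 23 genes 1 passed without the block, 9 when adjusted over the list alone, and 9 with the block (19 when adjusted over the list alone). The 9 were Foxp3, Il2ra, Il2rb, Gpr83 (2.09-fold, 467 ± 16.5 against 227 ± 54.5 CPM), Lrrc32 (1.85-fold), Socs2 (2.06-fold), Tnfrsf4, Ikzf4 and Swap70. The interleukin-2 and STAT5 list was higher as well (camera adjusted p = 2.9e-09, and adjusted p = 0.00564 with an estimated correlation), with 5 of 24 genes called with the block and 12 higher when adjusted over the list alone. Of its 18 genes outside the Treg core list, 1 was called with the block. Those 18 genes had a camera p of 0.0545 with an estimated correlation and the block. The conventional CD4 list was lower (camera adjusted p = 0.000354, 0.0445 with an estimated correlation); with the block Pde3b, Dapl1, Cd40lg and Ly6c1 were called, and the estimated correlation gave adjusted p = 0.106.

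Within the limits given for WT, the largest increases in the blocked TG fit were Pla2g4f (log2 1.95, SE 0.18), Rasip1 (log2 1.66, SE 0.17), Myb (log2 1.62, SE 0.22), Drc1 (log2 1.60, SE 0.24), Selp (log2 1.48, SE 0.27), Stra6 (log2 1.35, SE 0.22), Rec8 (log2 1.30, SE 0.20), Ntn4 (log2 1.15, SE 0.17), Gpr83 and Socs2. The largest decreases within them were Itga7 (log2 -1.46, SE 0.24), Cxcr3 (log2 -1.35, SE 0.21), Fasl (log2 -1.34, SE 0.22), Rflnb (log2 -1.22, SE 0.10), Vipr1 (log2 -1.18, SE 0.15), Pde3b (log2 -1.15, SE 0.24), Dapl1, Anp32a (log2 -1.10, SE 0.14), Tigit (log2 -1.09, SE 0.25) and Chil5 (log2 -1.07, SE 0.12). Below 10 CPM, Klrk1 was called with a larger decrease (log2 -3.48, SE 0.75, 0.0707 ± 0.122 against 0.920 ± 1.26 CPM).

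Other lists in TG passed with the preset correlation alone. Alpha chain segments were lower in 44 of 46 cases (median log2 -0.30, camera adjusted p = 5.04e-07, 0.0563 with an estimated correlation), beta chain segments in 17 of 21 (0.0334 and 0.896 likewise, 0.115 with the block). TCR immediate response genes, transcribed within minutes to hours of receptor signalling, were higher in 21 of 27 cases (0.00204 and 0.804 likewise), and naive or resting genes (0.036 and 0.924) and interferon-stimulated genes (0.036 and 0.924) were lower. With the block the effector Treg, helper lineage, adhesion, NF-kB, cell cycle, B cell, myeloid and CD8 or NK lists passed too (camera adjusted p = 1.12e-05 to 0.0359, 0.494 to 0.602 with an estimated correlation). The B cell list differed by 0.07, -0.66 and -0.19 in the 3 TG pairs, the myeloid list by -1.31, -0.16 and -0.21 and the CD8 or NK list by -1.61, -0.4 and 0.37. Csf1r and C1qb stood at 21.5 and 15.5 CPM (of unscaled totals) in TG Low replicate 1, and at 1.6 and 0.214 in TG High replicate 1. The direction of the CD8 or NK list turned without the 4 libraries numbered 1 (adjusted p = 0.0229 with the block, 0.0132 without it). Without the 4 libraries numbered 1 the count was 0 without the block and 39 with it, and leaving out TG High replicate 1 or TG Low replicate 1 alone gave 91 or 74 with the block. Without the block it was 0 without TG High replicate 1, TG High replicate 2 or TG Low replicate 2, 2 without TG High replicate 3 or TG Low replicate 3, and 3 without WT High replicate 2.

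Several of these list calls in TG ended when 1 library was left out. Without the block, the TCR immediate response call ended without TG High replicate 1 (adjusted p = 0.362), TG High replicate 3 (0.102) or TG Low replicate 2 (0.184). The interferon call ended without TG High replicate 1 (0.33), TG Low replicate 1 (0.0587) or TG Low replicate 3 (0.145). The naive or resting call ended without WT Low replicate 3 (0.0539), TG Low replicate 2 (0.285) or TG Low replicate 3 (0.88) and turned direction without TG High replicate 1 (0.825). The beta chain call ended without TG High replicate 1 (0.207), TG High replicate 2 (0.114), WT Low replicate 3 (0.0539), TG Low replicate 1 (0.135) or TG Low replicate 3 (0.77). With the block, leaving out TG High replicate 1 ended the TCR immediate response (0.242), naive (0.0766), interferon (0.138), NF-kB (0.29), cell cycle (0.627), myeloid (0.103) and CD8 or NK calls (0.961). Leaving out TG Low replicate 1 ended the effector (0.0786), adhesion (0.0525), interferon (0.343), cell cycle (0.0525), myeloid (0.812) and CD8 or NK calls (0.923). Leaving out TG Low replicate 3 ended the naive (0.324), interferon (0.523) and NF-kB calls (0.179), TG High replicate 3 the NF-kB (0.0561) and B cell calls (0.613), and TG High replicate 2 the interferon call (0.559). The B cell call also ended without WT High replicate 1 (0.0554), WT High replicate 3 (0.0518) or WT Low replicate 2 (0.0504), and turned direction without TG Low replicate 2 (0.96).

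The gate effects of the genotypes shared genes beyond an independent overlap. With the block 82 genes were higher and 47 lower in CD25 High in both WT and TG, where independent lists of these sizes would share 1.15 and 0.523 (Fisher's exact test, two-sided, p = 1.8e-152 and 7e-89), and 0 genes were called in opposite directions. Leaving out WT High replicate 1, TG High replicate 1, WT Low replicate 1 or TG Low replicate 1 gave 84, 76, 76 and 64 shared genes. Without the block the shared call was Il2rb, and DESeq2 shared 33. Across the 11766 genes, which are not independent replicates, the log2 changes of the genotypes correlated with r = 0.582 with the block. The comparisons shared no library, although libraries with the same number may share animals or a day. Both came from the same fit with the same variance estimate per gene, which can favour the same genes in both lists. Fisher's test also treats genes as independent, so its p-values and the independent overlap are descriptive.

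**Figure D3:**
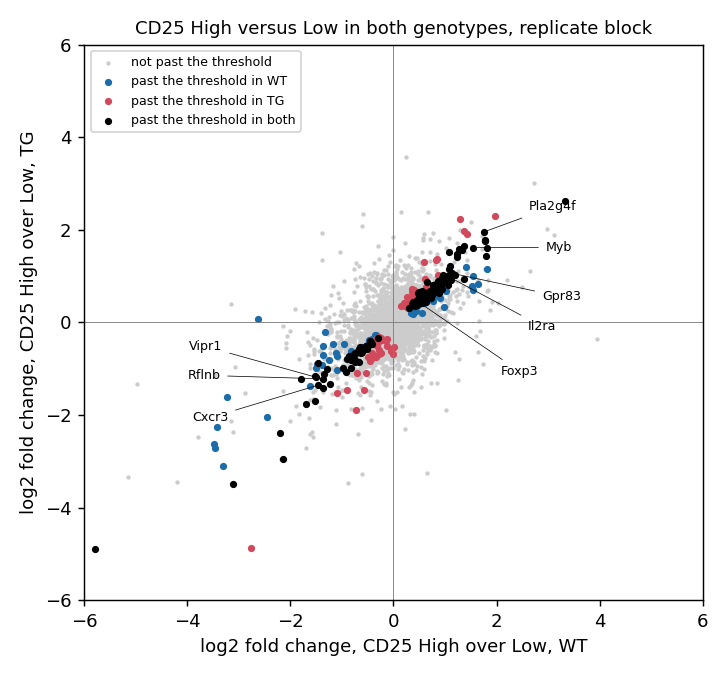
Log2 fold change of CD25 High over Low in WT (x axis) and in TG (y axis) for the 11766 tested genes, from the fit with the replicate block; black points passed the threshold in both genotypes, blue in WT alone and red in TG alone, and grey in neither. The 82 genes higher in both lie in the upper right and the 47 lower in both in the lower left.

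TG against WT in CD25 High cells. The comparison asks whether Atg5 loss in CD11c-expressing cells alters the RNA of CD25 High Tregs. The Treg genes had close levels in both genotypes: Foxp3 stood at 1525 ± 114 CPM in TG and 1550 ± 106 in WT (log2 difference with the block -0.02, 95% interval -0.18 to 0.14), Il2ra at 1183 ± 67.9 and 1190 ± 118 (-0.01, -0.18 to 0.17), Ctla4 at 259 ± 49.9 and 265 ± 44.5 (-0.04, -0.24 to 0.17) and Icos at 116 ± 60.5 and 101 ± 37.2 (0.13, -0.20 to 0.46; mean ± SD, n = 3 each). edgeR called no gene. Heat shock protein genes had higher values in TG, led by Hspa1a (32.0 ± 29.4 against 5.95 ± 2.80 CPM) and Hspa1b (94.6 ± 46.2 against 26.7 ± 16.3 CPM), and so had B cell genes. For Hspa1a, replicates 1, 2 and 3 stood at 65.8, 12.2 and 18.1 CPM in TG High and at 6.11, 3.08 and 8.67 in WT High.

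edgeR called 0 genes for genotype in CD25 High, with 99 at an unadjusted p under 0.05 where 588 would be expected by chance; DESeq2 and limma voom called 0 as well. With the block edgeR called 0 (418 at an unadjusted p under 0.05, smallest adjusted p 0.34). DESeq2 with the block called 10. The smallest adjusted p was that of Nwd1 (0.000656), with a fitted log2 change of -18.28. Rasl10b (-19.76) and Lepr (-15.73, adjusted p = 0.0163 each) had changes of that size too, and all 3 genes were below the count filter of the edgeR fit. The other 7 were Cd22 (adjusted p = 0.00767), Hsp90ab1 (0.0139), Sap130 and Il9r (0.0163 each), Hsph1 (0.0374), Iigp1 (0.0448) and Gm4951 (0.0471). Among genes with a mean of at least 10 CPM in the higher group and no predicted-gene symbol, the higher ones with the smallest p were Hspa1a, Suds3, Rwdd1, Hspa1b and B3gnt5, and the lower ones Sap130, Dcaf17, Rad54l2, Helb and Cog6, all with adjusted p of 1. With the block and the same limits they were, higher, the B cell inhibitory receptor gene Cd22 (log2 1.30, SE 0.23, adjusted p = 0.34), Hsp90ab1 (log2 0.45, SE 0.09, adjusted p = 0.377), Iigp1, an interferon-inducible GTPase (log2 0.49, SE 0.11, adjusted p = 0.501), Hsph1 (log2 0.53, SE 0.12, adjusted p = 0.607) and Stip1 (log2 0.33, SE 0.08, adjusted p = 0.921), and, lower, Sap130 (log2 -0.55, SE 0.11, adjusted p = 0.377), Zc3h12d, Dcaf17, Clec2d and Ubn2. Hspa1a and Hspa1b are near-identical neighbours on chromosome 17 (34969190 to 34972156 and 34956436 to 34959238, minus strand, GRCm38), so the split of reads between them is uncertain.

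All 13 heat shock genes had a positive difference in CD25 High (median log2 0.58), and the set passed camera with the preset correlation (adjusted p = 8.49e-13), though not with an estimated one (adjusted p = 0.183). The mean difference of the list was 0.91, 1.10 and 0.11 in the pairs of libraries numbered 1, 2 and 3. No member passed over all genes, and 4 passed with the block when adjusted over the list alone. The B cell list moved in the same pairs, with mean differences of 0.90, 1.08 and 0.03, all 17 genes positive (camera adjusted p = 0.00422, 0.991 with an estimated correlation), no gene called and 6 with the block when adjusted over the list alone. The other sets past the preset threshold, all higher in TG, were ribosomal proteins (76 of 85 positive), oxidative phosphorylation (67 of 77), interferon-stimulated genes (34 of 38), unfolded protein response (14 of 18), TCR immediate response (21 of 27) and gamma delta T cell genes (5 of 5), with camera adjusted p from 8.46e-13 to 0.011. An estimated correlation gave adjusted p from 0.183 to 0.991 for these. With the block the effector Treg, cell cycle, adhesion and myeloid lists passed too (camera adjusted p = 0.000244 to 0.0449, all 0.586 with an estimated correlation). With the block, 6 of the 11 calls that could be recomputed were kept without the 4 libraries numbered 1. With the block, leaving out WT High replicate 1 ended the effector (0.877), adhesion (0.715), TCR immediate response (0.289) and gamma delta calls (0.289) and turned the myeloid direction (0.715). Leaving out TG High replicate 1 ended the TCR immediate response call (0.774) and turned the cell cycle direction (0.731). The myeloid (0.383), gamma delta (0.187) and oxidative phosphorylation calls (0.262) ended without TG High replicate 2, and the effector (0.297), adhesion (0.71) and interferon calls (0.262) without TG High replicate 3. The ribosomal (0.294) and gamma delta calls (0.0941) ended without WT High replicate 2, the interferon call without WT High replicate 3 (0.0515), and the adhesion call without WT Low replicate 1 (0.0529), WT Low replicate 2 (0.0531) or TG Low replicate 3 (0.0564). Leaving out WT High replicate 2 or 3 ended the B cell call without the block (adjusted p = 0.489 and 0.675), leaving out TG High replicate 1 turned its direction (0.153), and leaving out WT High replicate 1 or 3 ended the interferon call (0.0862 and 0.347). Leaving out WT High replicate 2 ended the ribosomal (0.908), oxidative phosphorylation (0.82) and TCR immediate response calls (0.762). The last also ended without WT High replicate 1 (0.0651), TG High replicate 1 (0.941) or TG High replicate 3 (0.487), and oxidative phosphorylation without TG High replicate 1 (0.323). The gamma delta call, on 5 genes, held in 1 of 12 such fits (highest adjusted p 0.816). Of the lists that did not pass in either fit, Treg core (median log2 0.03, camera adjusted p = 0.475), interleukin-2 response (-0.01, 0.627) and autophagy (-0.002, 0.954) lay near 0.

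**Figure D4:**
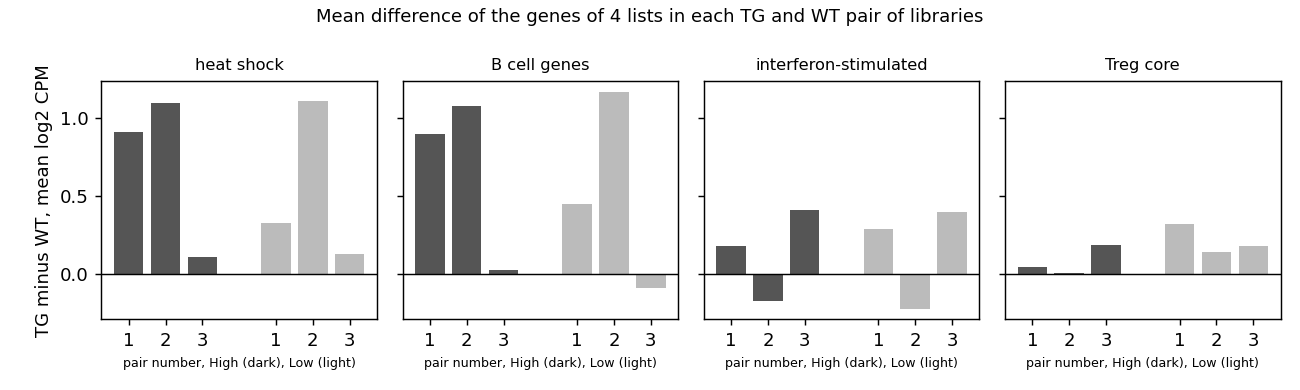
Mean difference in log2 CPM between TG and WT (y axis) over the genes of 4 lists in each pair of libraries with the same replicate number (x axis; dark bars, CD25 High; light bars, CD25 Low). The heat shock and B cell lists share their larger differences in the pairs numbered 1 and 2, while the interferon list is below 0 in both pairs numbered 2.

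TG against WT in CD25 Low cells. edgeR called no gene here either. Foxp3 stood at 1140 ± 48.7 CPM in TG and 1086 ± 101 in WT (log2 difference with the block 0.07, 95% interval -0.08 to 0.23), Il2ra at 593 ± 108 and 590 ± 131 (0.01, -0.16 to 0.19), Ctla4 at 198 ± 71.5 and 179 ± 47.6 (0.13, -0.07 to 0.34) and Icos at 166 ± 125 and 129 ± 75.6 (0.28, -0.05 to 0.60; mean ± SD, n = 3 each). The Treg core genes had small positive differences in 22 of 23 cases (median log2 0.16), among them Entpd1, which encodes the ectonucleotidase CD39 (37.6 ± 5.84 against 28.9 ± 0.757 CPM), and Capg (389 ± 80.9 against 318 ± 40.5 CPM). Heat shock and B cell genes were again on the higher side in TG.

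edgeR called 0 genes for genotype in CD25 Low (48 at an unadjusted p under 0.05, 588 expected by chance), and DESeq2 and limma voom 0. With the block edgeR called 0 (382 at an unadjusted p under 0.05, smallest adjusted p 0.141) and DESeq2 with the block called 2, Hsp90ab1 (adjusted p = 0.00576) and Gm4951 (0.00171). Leaving out WT High replicate 2 gave 2 edgeR calls with the block. Within the limits given for CD25 High, the smallest p belonged to Entpd1, Nefh, Arrdc4, Gbp10 and Ube2l6 among higher genes and to Nup133, Zfp609, Sfmbt2, Abca1 and Dip2a among lower ones, all with adjusted p of 1. With the block and within those limits Hsp90ab1 (log2 0.47, SE 0.09, adjusted p = 0.477), Stip1, Hsph1 and Gbp2 were among the higher genes with the smallest p, and Zfp512b (log2 -0.45, SE 0.11, adjusted p = 0.991), Zmym3, Rb1cc1, Per2 and Abca1 were the lower ones.

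Of the lists in CD25 Low, 11 passed with the preset correlation, all higher in TG. They were the Treg core list (camera adjusted p = 3.64e-06, 0.258 with an estimated correlation), heat shock (13 of 13 positive, 1.85e-08 and 0.258 likewise), interferon-stimulated genes (31 of 38 positive, 3.96e-08 and 0.46), oxidative phosphorylation (72 of 77), ribosomal proteins (70 of 85), unfolded protein response, glycolysis, effector Treg genes, alpha chain segments, B cell genes (17 of 17, 0.0205 and 0.795) and gamma delta T cell genes. For the 11 lists an estimated correlation gave adjusted p from 0.184 to 0.795. With the block 17 passed, 16 higher and 1, the naive or resting list, lower (camera adjusted p = 0.0423), and an estimated correlation gave 0.119 or more for each. Without the 4 libraries numbered 1, 8 of 16 recomputed calls were kept with the block and 6 of 10 without it. With the block, leaving out TG Low replicate 1 ended the naive (0.464), NF-kB (0.203), gamma delta (0.0522) and alpha segment calls (0.176) and turned the direction of costimulatory (0.618), adhesion (0.809) and myeloid genes (0.595). Leaving out WT Low replicate 1 ended the naive (0.275), costimulatory (0.0507), adhesion (0.117), NF-kB (0.388), glycolysis (0.117) and alpha segment calls (0.113) and turned the cell cycle direction (0.617). The naive (0.369), NF-kB (0.402), cell cycle (0.478) and gamma delta calls (0.155) ended without TG Low replicate 2, and the naive (0.0669), costimulatory (0.0659), adhesion (0.688), gamma delta (0.0952) and alpha segment calls (0.0952) without WT Low replicate 3. The glycolysis and alpha segment calls (0.265 each) ended without TG Low replicate 3, the naive call without WT High replicate 1 (0.0507) and the adhesion call without WT High replicate 2 (0.0533). The mean heat shock difference was 0.33, 1.11 and 0.13 in the pairs numbered 1, 2 and 3, and that of B cell genes 0.45, 1.17 and -0.09. Without the block, leaving out TG Low replicate 2 ended the heat shock (adjusted p = 0.42) and B cell calls (0.0815), and leaving out TG Low replicate 1 ended the Treg core (0.0659), oxidative phosphorylation (0.546), unfolded protein response (0.113), glycolysis (0.214) and alpha segment calls (0.0931) and turned the B cell direction (0.0734). Leaving out WT Low replicate 3 ended the interferon (0.167), glycolysis (0.139) and alpha segment calls (0.0645) and turned the B cell (0.861) and effector directions (0.217). The B cell (0.612) and effector calls (0.264) also ended without WT Low replicate 2. The effector direction turned without TG Low replicate 1 (1.79e-05), alpha segments were lost without WT Low replicate 1 (0.11) or TG Low replicate 3 (0.144), glycolysis without TG Low replicate 3 (0.0592), and the gamma delta call held in 1 of 12 such fits (highest adjusted p 0.724).

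The genotype effect averaged over both gates was added after seeing the data. Without the block edgeR called 0 genes (DESeq2 and limma voom 0). With it edgeR called 6, all higher in TG: Gm4951, an interferon-inducible GTPase gene (log2 1.32, SE 0.17, adjusted p = 0.00823), Hsp90ab1 (log2 0.46, SE 0.06, adjusted p = 0.0131), Cd22 (log2 1.04, SE 0.15, adjusted p = 0.022), Il9r (log2 0.80, SE 0.13, adjusted p = 0.0484), Hsph1 (log2 0.51, SE 0.08, adjusted p = 0.0484) and Stip1 (log2 0.34, SE 0.06, adjusted p = 0.0484). Hsp90ab1, Hsph1 and Stip1 encode cytosolic chaperones or their partners, and Cd22 is on the B cell list, whose mean difference lay above 0 in 5 of 6 pairs. That fit counts the High and Low libraries of a genotype and number as independent, although their TG to WT differences repeated by number. With their counts summed, so that 3 pairs were tested, edgeR with the block called 0 genes (624 of 11984 at an unadjusted p under 0.05). The adjusted p were then 0.0526 for Gm4951, 0.121 for Hsp90ab1 and Il9r, 0.195 for Cd22, 0.208 for Stip1 and 0.493 for Hsph1. DESeq2 with the block on the 12 libraries called 38, and the edgeR count on them was 0 without the 4 libraries numbered 1. It was 1 without WT Low replicate 1, 2 or 3, 2 without WT High replicate 1 or 2, and 3 without TG High replicate 1, TG Low replicate 1 or TG Low replicate 3.

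Difference of the genotype effects between the gates. edgeR called 0 genes for a genotype effect that differed between CD25 High and CD25 Low (27 at an unadjusted p under 0.05, 588 expected by chance), DESeq2 and limma voom 0. A count below 588 means that the p-values ran high, so 0 calls do not show equal effects. The block held the replicate number alone, and neither fit paired the High and Low libraries of a genotype and number beyond it. With the block edgeR called 0 (118 at an unadjusted p under 0.05) and DESeq2 with the block called 2, Ighv15-2 (adjusted p = 0.000246) and Thpo (adjusted p = 0.000372), which had 9 and 7 counts in total, each from 2 libraries. The difference for Il2ra was -0.02 on the log2 scale (95% interval with the block -0.27 to 0.23), for Foxp3 -0.09 (-0.32 to 0.13), for Ctla4 -0.17 (-0.46 to 0.12) and for Icos -0.15 (-0.61 to 0.32). Within the limits given for CD25 High, genes with the smallest p included Dip2a, Suds3, Zmym4, Abhd17b and Abcg2 on the positive side and Sap130, Helb, Cyhr1 and Stk11 on the negative side, all with adjusted p of 1.

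As a set, Treg core genes differed in genotype effect between the gates with the block (21 of 23 lower in CD25 High than in CD25 Low, median log2 -0.09, camera adjusted p = 0.00723, 0.941 with an estimated correlation) and not without it (0.0506). TCR immediate response genes differed the other way (21 of 27, median log2 0.14, camera adjusted p = 0.0373 with the block, 0.941 with an estimated correlation, 0.0728 without the block). The Treg core call ended without WT High replicate 2 (0.0595), TG High replicate 1 (0.0698), WT Low replicate 1 (0.101) or TG Low replicate 1 (0.188). The TCR call turned direction without TG High replicate 1 (0.979) and ended without WT High replicate 1 (0.299), TG High replicate 3 (0.0622), WT Low replicate 2 (0.308), WT Low replicate 3 (0.0551), TG Low replicate 1 (0.133) or TG Low replicate 3 (0.0775). The genotype effects of the gates shared 0 called genes and correlated across genes with r = 0.295 without and 0.267 with the block. Lists that were tested in no comparison, having under 5 tested genes, gave counts of 0 called members in every comparison over all genes: mitochondrially encoded (0 tested), sex-linked (4), neutrophil (1), plasma cell (4) and erythroid or platelet genes (2).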

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

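The tests of B cell RNA and of the genotype of the mice were chosen only after the result was seen, as were those of the animals or day of replicate 1. Groups of 3 libraries are too small for the outlier test used for groups of 4 to 10, so no library was tested as an outlier. As a set, Treg core genes had a smaller genotype effect in CD25 High than in CD25 Low with the block (adjusted p of the difference 0.00723), and TCR immediate response genes a larger one (0.0373); neither passed with an estimated correlation (0.941 for both). For 8 of 120 named genes, 4 of them named for the difference of effects, TG lay above WT in all 3 pairs of one gate and below it in all 3 of the other, and this difference was not tested by that rule. The differences of log2 fold changes were 0.39 for Abcg2, 0.5 for Acpp, 0.86 for Dip2a, 1.49 for Klrd1, 0.14 for Rflnb, -0.34 for Ccr9, -0.55 for Helb and -0.81 for Clec2d, each with an adjusted p of 0.9999 in edgeR. Klrd1 lay between 0 and 2.57 CPM in the 12 libraries. Among all 11766 tested genes 162 had such a pattern.

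The 4 libraries numbered 1 stood apart from the others. After thinning every library to 6767828 counts the gap on the first component was at least 40.3 (43.1 before), which argues against sequencing depth. RNA from B cells stays open for the B cell genes: 17 of 17 were called higher in replicate 1, but this is the observation itself and no independent test was run, and the sort for CD4 would remove such cells. For the effector Treg genes, 39 of which were higher, the animals or the sort day of replicate 1 stay open, since the labels give neither.

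B cell genes were higher in TG than in WT in both gates for 17 of 17 members. RNA from B cells in the sorted cells stays open, since this count is the observation itself. The members with the highest mean CPM were Ighm (534 ± 163 CPM in TG High, 447 ± 109 in WT High, mean ± SD, n = 3), which differed by -0.02 and -0.11 in the pairs numbered 2 of CD25 High and CD25 Low, Igkc (62.3 ± 89.2 and 33.2 ± 45.6 CPM) and Cd79b (43.8 ± 29.4 and 32.0 ± 17.6 CPM), and 1 of the 17, Blk, is also on the gamma delta list. The genotype of the mice stays open as the reason: the list was higher in TG in 5 of 6 pairs of libraries, and a varying share of B cells between sorts could give the same, so these cannot be told apart with 3 replicate numbers.

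Of the 10 splits of 6 libraries, 1, the real one, gave as many genes for the gates in WT (6, highest other 0) and in TG (1, highest other 0), and all 10 did for genotype in either gate (0, highest other 0). With the block, of 4 splits that part as many pairs, 1 gave as many in WT (192, highest other 1) and in TG (198, highest other 0), and all 4 for genotype in either gate (0, highest other 0). These splits are too few for a share under 0.05. For the difference of effects the real count was 0, so all 100 drawn splits gave at least as many by construction (highest other 20), and the splits say nothing of chance there or for the other counts of 0.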

How the results depend on the processing

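The fits with the replicate block other than the planned one, the averaged genotype effect and the fits without all libraries of a number were chosen after seeing the data. With the replicate block the counts of called genes became 192 for the gates in WT, 198 for the gates in TG, 6 for the averaged genotype effect and 129 for the overlap, and the count stayed 0 for genotype in either gate and for the difference of effects. DESeq2 gave 47 and 56 genes for the gates in WT and TG with 33 shared, and limma voom 14 in WT. Fitting only the libraries compared gave 1 in WT and 0 in TG. For TG, upper-quartile factors gave 2, no low-count filter 3 (overlap 3) and at least 5 CPM in 3 libraries 3. Without the 4 libraries numbered 1 both gate counts were 0. DESeq2 with the block gave 10 genes for genotype in CD25 High, 2 in CD25 Low, 334 for the gates in TG, 2 for the difference of effects and 38 for the averaged effect. Also with the block, leaving out the libraries numbered 1 gave 49 and 39 for the gates in WT and TG and 0 for the averaged effect, leaving out those numbered 2 gave 6 for genotype in CD25 Low and 36 for the averaged effect, and leaving out those numbered 3 gave 21 for the averaged effect. The averaged count was 12 with no low-count filter, 1 with at least 5 CPM in 3 libraries, 2 without other-cell and segment genes and 0 with the High and Low counts of a genotype and number summed, which tests 3 pairs. The cause of these changes was not tested.

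Leaving out each library in turn, the count ran from 0 to 7 for the gates in WT, from 0 to 3 in TG and from 0 to 2 for the overlap. With the block it ran from 0 to 2 for genotype in CD25 Low, from 87 to 247 for the gates in WT, from 74 to 235 in TG, from 1 to 8 for the averaged effect and from 64 to 126 for the overlap. Among the named genes with the block, 1049 of 1228 values for the gates in WT and 855 of 957 in TG kept their side of the threshold. In WT and TG, 179 and 97 values fell short of it, and 0 and 5 gained a call. Where a gene was called in the main or the altered fit, 0 values turned direction. Among genes called in neither fit, 1 value in WT and 5 in TG did. Of the named genotype genes, none was called in the 701 and 789 values for CD25 High and Low that alter the fit without the block. Of those that alter the fit with the block, 5 of 637 and 4 of 717 gained a call. These were Cd22, Hsp90ab1, Sap130, Hsph1 and Iigp1 in High and Hsp90ab1 in Low with DESeq2, and in Low Hsp90ab1 and Bst2 without the libraries numbered 2 and Hsp90ab1 without WT High replicate 2. The Treg core and interleukin-2 lists kept their calls for the gates in all 16 settings of either fit, and the conventional CD4 list did so except in TG with the block (15 of 16). The block changed other list calls as the report gives. With the block but without the libraries numbered 1, 9 of 13 list calls were kept for the gates in WT, 10 of 15 in TG, 6 of 11 and 8 of 16 for genotype in High and Low and 0 of 2 for the difference of effects.

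Without the 4 libraries numbered 1, CD8 or NK genes turned direction for the gates in TG (adjusted p = 0.0132, and 0.0229 with the block) and in WT with the block (0.209), and TCR immediate response genes for genotype in CD25 High with the block (0.939). Without those numbered 2, with the block, ribosomal genes turned for the gates in WT (1.07e-06) and for the difference of effects (0.000275). For lists whose direction turned with 1 library left out, the lowest and highest camera adjusted p follow, over all 12 such fits where the list was called with all libraries, and otherwise over the fits in which a call arose. The cause was not tested. For genotype in High, they ran from 1.11e-05 to 0.00341 for activated or effector Treg, from 5.81e-09 to 0.0443 for cell cycle, from 2.81e-08 to 0.675 for B cell, from 0.00102 to 0.0403 for naive or resting T cell, to 0.0105 alone for helper T lineage and cytokine. For genotype in Low, they ran from 1.73e-11 to 0.264 for activated or effector Treg, from 2.66e-08 to 0.861 for B cell, from 0.000207 to 0.0353 for naive or resting T cell, from 0.000757 to 0.0323 for costimulatory and coinhibitory receptors, from 0.00264 to 0.0362 for helper T lineage and cytokine, from 7.66e-06 to 0.000903 for cell cycle, from 3.62e-05 to 0.015 for myeloid or dendritic cell, from 1.86e-05 to 0.0316 for CD8 T or NK cell. For gates in WT, they ran from 7.19e-05 to 0.00973 for activated or effector Treg, from 8.03e-06 to 0.0333 for cell cycle, from 0.000672 to 0.0401 for oxidative phosphorylation, from 6.6e-07 to 0.0342 for ribosomal protein, from 1.42e-05 to 0.0418 for B cell. For gates in TG, they ran from 6.83e-07 to 0.88 for naive or resting T cell, from 5.75e-07 to 0.00976 for activated or effector Treg, from 3.56e-06 to 0.00889 for cell cycle, from 8.31e-06 to 0.0344 for oxidative phosphorylation, from 0.000221 to 0.0443 for B cell, from 0.0021 to 0.0136 for myeloid or dendritic cell. For difference of effects, they ran from 1.73e-07 to 0.0462 for cell cycle, from 8.35e-08 to 0.00805 for oxidative phosphorylation, from 2.1e-08 to 0.0358 for ribosomal protein, from 2.26e-05 to 0.0412 for B cell, from 6.66e-07 to 0.0462 for interferon-stimulated, from 1.23e-06 to 0.0462 for activated or effector Treg, from 0.00617 to 0.0203 for helper T lineage and cytokine, from 1.19e-06 to 0.0183 for myeloid or dendritic cell, from 0.00668 to 0.0266 for costimulatory and coinhibitory receptors, from 0.000724 to 0.042 for CD8 T or NK cell. With the block, for genotype in High, they ran from 5.44e-08 to 0.731 for cell cycle, from 3.53e-08 to 0.715 for myeloid or dendritic cell. With the block, for genotype in Low, they ran from 0.00029 to 0.618 for costimulatory and coinhibitory receptors, from 0.000936 to 0.809 for adhesion and chemokine receptors, from 6.21e-06 to 0.617 for cell cycle, from 2.66e-08 to 0.595 for myeloid or dendritic cell. With the block, for gates in WT, they ran from 0.000165 to 0.0287 for ribosomal protein. With the block, for gates in TG, they ran from 0.0023 to 0.96 for B cell. With the block, for difference of effects, they ran from 2.71e-08 to 0.979 for TCR immediate response, from 5.23e-05 to 0.037 for ribosomal protein, from 0.00466 to 0.0325 for myeloid or dendritic cell. The smallest library, TG High replicate 2 with 6767828 counts, limits the genes near the floor, and 3 libraries per group limit small differences, as the recovery on simulated counts gives.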

Other observations

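The tests of Foxp3-expressing cells were chosen only after the result was seen. Levels of Y-linked genes varied with the replicate number and, in number 3, between the genotypes. Ddx3y had 44.4, 205 and 103 CPM (of unscaled totals) in WT High replicates 1, 2 and 3, 51.5, 199 and 141 in TG High, 40.8, 173 and 97.2 in WT Low and 51.7, 202 and 128 in TG Low. Eif2s3y had 34.7, 101 and 57.9 CPM in WT High, 35.8, 98.1 and 119 in TG High, 37.3, 89.1 and 61.7 in WT Low and 35.6, 89.8 and 109 in TG Low. Uty had 26.5 CPM in WT High and 56.1 in TG High replicate 3, and 30.4 and 46.9 in Low. A mix of male and female mice that differs between the genotypes was not tested and stays open for the TG to WT values. Ddx3y was called higher in TG for the averaged genotype effect by DESeq2 with the block (log2 0.29, SE 0.07, adjusted p = 0.0105) and not by edgeR. Variable segments of the T cell receptor alpha chain had a lower mean in CD25 High in all 6 pairs of libraries, by -0.19, -0.23 and -0.25 on the log2 scale in WT and by -0.37, -0.3 and -0.35 in TG. Most segments moved the same way, and the cause was not tested.

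The Treg core list was lower as a set in CD25 Low than in CD25 High. A smaller share of Foxp3-expressing cells in CD25 Low stays open as the whole cause. Of 21 other members, 16 did not differ by more than Foxp3, beyond the 95% interval from the combined SE, in either genotype. The 4 that did in both, Il2rb, Gpr83, Lrrc32 and Socs2, were picked out by the size of their change. For the members not beyond Foxp3 such a smaller share may account for the pattern in WT, where the conventional CD4 list was higher in CD25 Low (adjusted p = 0.03 with an estimated correlation and the block), and stays open in TG (0.106). A stronger interleukin-2 and STAT5 response in CD25 High is a hypothesis consistent with the 18 response genes outside the Treg core list in WT (camera p = 0.00998 with an estimated correlation and the block), and stays open in TG (0.0545). Il2ra was itself sorted on, so its difference follows from the gates.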
